A study of Caenorhabditis elegans with 2 samples.

How the data were processed

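Whole young adult worms of strain OP594 were sampled 63 h after synchronisation, in 2 biological replicates of 1 group, per the labels. Chromatin was sheared by sonication and recovered with an anti-GFP antibody, per the labels, although the antibody field there names FKH-3 itself. The deposited lists are in narrowPeak format on ce11 and ce10. The authors deposited, for each replicate and for both pooled, the regions that served as input for the IDR step, and for the pooled data the regions past the IDR threshold. The peak caller, the aligner and their versions are not given in the sources used here. The deposited signal of a region is a score on a scale that is not stated, and the lists also hold the −log10 of the authors' q-value and the position of the summit. Scores were compared only as ranks within a list. Each 30000-region list covered 10.9 to 12.0% of the genome with regions of nearly 1 width per list (364 bp in replicate 1, 400 bp in replicate 2 and 390 bp pooled). It therefore includes background. All 441 IDR regions were the top 441 of the pooled list by signal. The lists hold no read counts, so depth and its effect on precision are unknown, and the intervals given cover counting error of regions only.

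Summits on ce11 were annotated with Ensembl 115 gene models of WBcel235, the same assembly, and with its RefSeq sequence. All 30000 pooled regions lay within its chromosome lengths. The ce10 lists were only counted, since no annotation of that build was used here. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. IDR summits were compared with the 29559 pooled summits outside IDR regions by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 7 annotation classes, 6 chromosomes, 33 gene lists or 2080 words, at a threshold of 0.05. Classes were assigned in the order promoter, 5'UTR, 3'UTR, coding exon, intron, noncoding-RNA gene and intergenic. For gene lists the background was the 6784 protein-coding genes with a pooled region in the same window. Neighbouring genes can share a region, and downstream genes of operons may lack a promoter of their own. Motif and word searches used 201-bp windows on both strands, with 5 GC-matched windows per summit. tRNA isotypes came from RefSeq, which matched 607 of 612 genes.

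The tests, the gene lists, the other settings to try and the rule for named genes were fixed before the data were examined. The rule took the 25 IDR entries of highest signal with the nearest protein-coding start, *fkh-3*, *fkh-4*, *fkh-5* and *unc-119*, up to 4 members of each list that passed, and up to 4 forkhead family genes with an IDR region. The test by small RNA gene type, the summit offsets, the isotypes, the top 5000 regions at the transgene loci, motif settings that change 2 choices together and all settings without summits at small RNA genes were chosen after the data had been seen. The rank correlation between replicates is not reported here. The design names both flanks and GC-matched windows for the motif, and both are reported.

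The procedures were tested on simulated data made by drawing 441 regions at random from the pooled list, 20 times with nothing planted and 20 times with regions added at ribosomal protein genes, promoters, X and tRNA genes and with motifs inserted. The planted draws passed in 20 of 20 for the ribosomal list, promoters, X and tRNA genes. The motif passed in 20 of 20 against GC-matched windows and 18 of 20 against flanks. The planted motif had odds ratios of 1.94 to 2.90 against GC-matched windows, above the 1.33 of the IDR list. More regions were planted at ribosomal protein genes than there were members with an IDR summit. Whether effects of the size found in the IDR list would pass in those tests was not tested. With nothing planted, the ribosomal list and X each passed in 1 of 20 draws and promoters and tRNA genes in 0. All 20 draws had a motif odds ratio below 1 against flanks (0.491 to 0.906), 11 of them with p under 0.05, so the flank comparison is biased downward for random regions of these lists. Against GC-matched windows the median was 1.01, and 1 draw lay below with p under 0.05.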

Results

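Binding of FKH-3, a forkhead transcription factor of *Caenorhabditis elegans*, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult worms of mixed sex, 63 h after synchronisation at the starved L1 stage. The worms carried an integrated transgene for FKH-3 with a C-terminal GFP-FLAG tag, and chromatin was recovered with an antibody against GFP. There was 1 group of 2 biological replicates, so no condition was compared with another. The comparisons are between regions of the genome and between the replicates. Each replicate had a list of 30000 regions that holds peaks together with background, the pooled replicates had another list of 30000, and 441 regions of the pooled list passed the irreproducible discovery rate (IDR) threshold. These were the 441 of highest signal in the pooled list. Read depth is unknown, because the lists give no read counts, and the signal of a region is the authors' own score, used here as a rank within its list. Coordinates are on ce11. Regions are not biological replicates, so each p-value describes these lists. The matched control was not analysed here.

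The strongest feature of the IDR list was its concentration at genes for small structural RNAs. Of 441 IDR summits, 23.6% (exact 95% confidence interval 19.7 to 27.8%) lay within 100 bp of a tRNA gene, against 1.04% of the 29559 other summits of the pooled list (odds ratio 29.3, Fisher's exact test, two-sided, adjusted p = 9.4e-98 over 10 gene types). Genes for snoRNAs, which guide the modification of other RNAs, held 52 summits (11.8% against 0.318%, odds ratio 41.9, adjusted exact p = 4.6e-57). Genes annotated as snRNA, a type that here includes spliced-leader RNA genes, held 9 (2.04% against 0.162%, odds ratio 12.8, adjusted exact p = 3.6e-07). Together these types took 165 of 441 summits (37.4%) against 1.52% (odds ratio 38.8). In replicate 1 alone the tRNA odds ratio was lower, at 17.1 with 66 summits, and the combined one was 24.4 with 114. For snRNA genes it was 12.2 with 7 summits in replicate 1 alone and 20.1 with 14 in replicate 2 alone. With the summit inside the gene, 62 summits were left at tRNA genes, 11 at snoRNA genes and 74 in all. The broad annotation type ncRNA, which overlaps these genes in part, held 113 summits (25.6% against 5.17%, odds ratio 6.32, adjusted exact p = 3.2e-44), and 29 of the 276 summits away from tRNA, snoRNA and snRNA genes (10.5% against 4.46%, odds ratio 2.52, adjusted p = 2.6e-04). Counted by gene, 114 of 612 tRNA genes, 53 of 346 snoRNA genes and 9 of 129 snRNA genes had an IDR summit. Genes for piRNAs, small RNAs of the germ line, had 0.454% of IDR summits against 0.416% (odds ratio 1.09, adjusted exact p = 0.884), and microRNA genes had 2 summits (adjusted p = 0.244). This gene-type test was chosen after the data had been seen. tRNA genes exist in similar copies, and a median of 25.9% of the 36-base words in the windows around the tRNA summits recurred elsewhere in the reference.

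**Figure D1:**
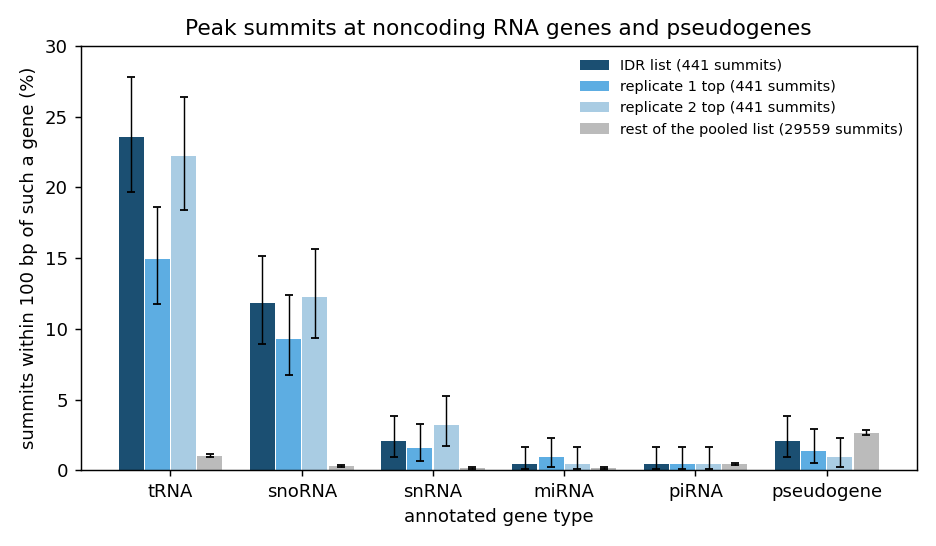
Share of summits (%) within 100 bp of an annotated gene of each type, for the IDR list, the 441 regions of highest signal in each replicate and the other regions of the pooled list; bars are shares and error bars are exact 95% confidence intervals, which cover counting error only. tRNA genes took 15% of the top summits in replicate 1 and 22.2% in replicate 2, against 1.04% in the rest of the pooled list.

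The position of the summit differed between tRNA and snoRNA genes. At tRNA genes the median summit was 40 bp downstream of the annotated 5' end, and 62 summits were inside the gene. At snoRNA genes the median summit was at -23 bp, and 39 of 52 (75%) were upstream of the 5' end, against 18.3% at tRNA genes (odds ratio 13.4, Fisher's exact test, two-sided, p = 7.6e-12). In the top 441 of each replicate the snoRNA share upstream was 75.6% in replicate 1 and 68.5% in replicate 2, and the tRNA share was 24.2% and 19.4%. At the other pooled summits the median was 33 bp at tRNA genes, with 30.8% upstream, so the tRNA median of the IDR list was near it. At snoRNA genes it was 46 bp, with 29.8% upstream, and the genes there were longer (median 132.5 against 83 bp). These comparisons were also chosen after the data had been seen.

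**Figure D2:**
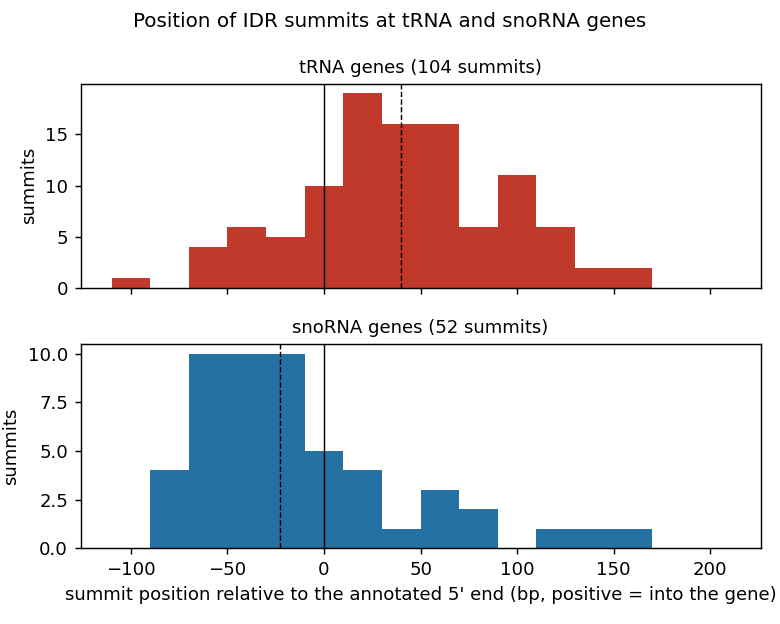
Number of IDR summits by distance (bp) from the annotated 5' end of the tRNA or snoRNA gene within 100 bp; the solid line is the 5' end and the dashed line the median. The median was 40 bp for tRNA summits, near the 33 bp of the other pooled summits at tRNA genes. It was -23 bp for snoRNA summits, against 46 bp for the other pooled summits at snoRNA genes.

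The region of highest signal lay inside *snpc-4*, the gene for a subunit of the complex that activates snRNA gene transcription. It spanned chromosome I from 8962813 to 8963490, with 2 summits in the pooled list, at 8963235 in coding exon 3 and at 8963014 in coding exon 2. The same place ranked 1 in both replicates. Among the 25 highest entries of the IDR list, 13 were at tRNA, snoRNA or snRNA genes, 9 of them snoRNA and 4 tRNA genes. The 3rd entry, on chromosome V from 8500420 to 8500710, was at a snoRNA gene in an intron of *pxn-1*. Other snoRNA entries had *F55C5.17*, *W03C9.1*, *cutl-18*, *str-56*, *sre-23*, *wrt-3*, *Y23H5B.5* and *twk-5* as the nearest protein-coding start. The tRNA entries had *F15G9.5*, *C04A11.5*, *M02F4.2* and *srd-43*. The entry nearest *F15G9.5*, on X from 9743463 to 9743852, lay in an intron of *him-4* and held a pair of tRNA-Ala genes. Entries at no gene of these types were nearest the starts of *zip-2*, *ints-8*, *mdt-26*, *kel-3*, *cgh-1*, *rpl-3*, *hrg-5*, *Y37A1B.7*, *kin-14* and *prmt-5*. The summit nearest *zip-2* lay 1697 bp from its start, inside *dos-3*, and the one nearest *kel-3* lay in *cdk-5* and *ant-1.1*. The one nearest *cgh-1* lay on the ncRNA genes *C07H6.15* and *C07H6.17*. The *ints-8* entry, on chromosome I from 13463869 to 13464075, held *rpr-1*, the RNA of RNase P. The entries nearest *hrg-5* and *Y37A1B.7* had their summits on the microRNA genes *cel-mir-51* and *cel-mir-52*, the only microRNA summits of the IDR list. The RNA genes, *him-4*, *dos-3*, *cdk-5* and *ant-1.1* were named after their values were seen. *kel-3* (-107 bp), *rpl-3* (-290 bp), *kin-14* (40 bp) and *wrt-3* (-261 bp) had the summit in the promoter window. All 25 entries were in the top 441 of both replicates, with worst ranks of 72 and 33.

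**Figure D3:**
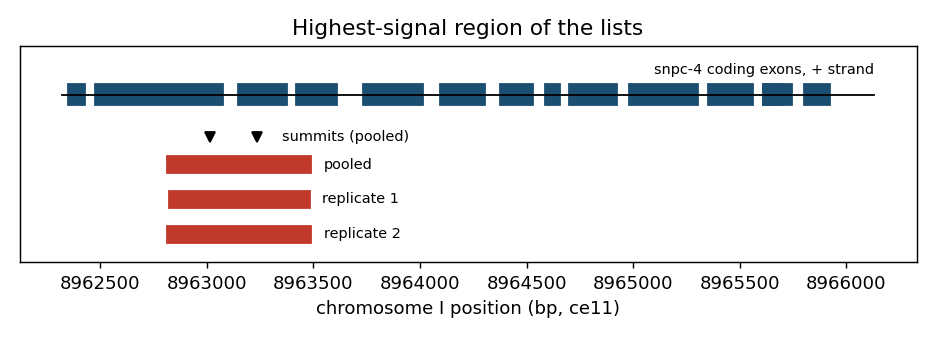
Map of *snpc-4* on chromosome I (position in bp, ce11) with its coding exons in blue, the region as called in the pooled list and in each replicate in red, and the pooled summits as triangles. The region covers 561 bp of coding sequence and 117 bp of intron.

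By annotation class, noncoding-RNA genes held 49 IDR summits (11.1%) against 1.56% of the other pooled summits (odds ratio 7.87, adjusted p = 1.4e-24, Fisher's exact test with Benjamini-Hochberg adjustment over 7 classes). The odds ratio was 4.76 in replicate 1 alone, with 29 summits, and 3.83 without the summits at small RNA genes, with 13. Promoters of protein-coding genes, from 500 bp upstream to 100 bp downstream of a transcript start, held 91 (20.6% against 15.2%, odds ratio 1.45, adjusted exact p = 0.0061). Coding exons held 18.1% against 33.1% (odds ratio 0.448, adjusted exact p = 1.7e-11). Introns (22% against 26.1%, adjusted exact p = 0.0861), intergenic sequence (23.4% against 19.7%, adjusted p = 0.0861), 5'UTRs (1.36% against 0.869%, adjusted p = 0.34) and 3'UTRs (3.40% against 3.50%, adjusted p = 1) did not pass. The 5'UTR odds ratio was 1.57, with 1.47 in replicate 1 alone and 0.742 in replicate 2 alone. The 3'UTR odds ratio was 0.969, with 1.55 in replicate 1 alone and 1.14 in replicate 2 alone, and none of these passed. The promoter call was lost in replicate 1 alone (odds ratio 1.32, adjusted exact p = 0.0733) and with a window of 250 bp upstream to 50 bp downstream (odds ratio 1.07, adjusted p = 0.783). Against random positions the coding exon call was lost (odds ratio 0.787, adjusted exact p = 0.0796), introns passed at 0.645 (adjusted p = 3.3e-04) and intergenic sequence turned to 0.753 (adjusted p = 0.0199). Without the summits at small RNA genes, a setting chosen after the data had been seen, introns passed at 0.43 (adjusted exact p = 2.4e-06), and 5'UTRs at 2.53 and intergenic sequence at 1.36 passed too (adjusted p = 0.0423 for both).

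The X chromosome held 87 of 441 IDR summits (19.7%), against 19.6% of the other pooled summits (odds ratio 1.01, adjusted p = 0.952 over 6 chromosomes, Fisher's exact test). Chromosome V held fewer (14.5% against 21.2%, odds ratio 0.633, adjusted exact p = 0.003) and chromosome III more (18.6% against 14.3%, odds ratio 1.37, adjusted p = 0.0406). X carried 276 of the 612 tRNA genes, and 55 of the 165 summits at small RNA genes. Without those 165, X held 32 of 276 summits (11.6% against 19.4%, odds ratio 0.545, adjusted exact p = 0.0021), a setting chosen after the data had been seen. Against the number of protein-coding genes, X held more (odds ratio 1.55, adjusted exact p = 0.0014). In replicate 1 alone neither V (odds ratio 0.721, adjusted exact p = 0.067) nor III (odds ratio 1.29, adjusted p = 0.0949) passed.

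None of the 33 gene lists passed the test for IDR summits near transcript starts (Fisher's exact test with Benjamini-Hochberg adjustment), and 2 had an unadjusted p under 0.05. A summit lay within 1000 bp upstream to 200 bp downstream of a start for 177 of the 6784 genes with a listed region there. Cytosolic ribosomal protein genes came closest, with 6 of 49 members (12.2%) against 2.54% of other genes (odds ratio 5.36, exact p = 0.0016, adjusted p = 0.0527). These were *rpl-3*, *rps-16*, *rpl-20*, *rpl-35*, *rpl-15* and *rps-26*, with summits from -444 to 91 bp relative to the start. The *rps-26* summit was also within 100 bp of a snoRNA gene. The *rpl-20* summit was nearer the start of *Y17G9B.5* (-158 bp) than that of *rpl-20* (-304 bp). This list passed under 6 of 8 other settings, among them replicate 2 alone (odds ratio 7.19, adjusted exact p = 0.0044). It did not pass in replicate 1 alone (odds ratio 5.48, adjusted exact p = 0.115) or with each summit counted for its nearest gene only (odds ratio 3.96, adjusted p = 0.599). Heat shock protein genes had 2 of 10 members, *hsp-60* and *hsp-3* (exact p = 0.0265, adjusted p = 0.438). Seven-pass chemoreceptor genes had 4 of 229 (adjusted exact p = 1), nuclear hormone receptors 1 of 95 and cuticle collagens 1 of 60. The lists of intestine, body wall muscle, synaptic, meiosis and sperm genes had 0 members with a summit, out of 16, 22, 26, 18 and 12. Histones, proteasome subunits and other lists had 0 too. A count of 0 in lists this small says little, since only 177 of the 6784 genes had a summit. Of 12 forkhead family genes in the background, *pha-4*, which specifies the pharynx, had a summit at -400 bp from its start, ranked 614 in replicate 1 and 803 in replicate 2. The members named of lists that did not pass were chosen after their values were seen.

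The forkhead family motif RTAAAYA occurred within 100 bp of 53 of 441 IDR summits (12%). The share was 9.30% in windows of the other pooled regions matched on GC content (odds ratio 1.33, 95% confidence interval 0.947 to 1.85, p = 0.0942, Fisher's exact test, two-sided), and 19.8% in flanks 300 to 500 bp from the same summits (odds ratio 0.552, p = 3.7e-04). The direction thus differed between the comparisons. The median GC content was 44.8% at the summits and 35.8% in the flanks, and random draws of 441 regions from the pooled list also lay below their flanks, with odds ratios from 0.491 to 0.906 in 20 draws, 11 of them with p under 0.05. The stricter motif GTAAACA was at 2.72% of summits, 2.38% of flanks (exact p = 0.711) and 1.81% of GC-matched windows (p = 0.257). Within 250 bp, RTAAAYA was at 38.1% of summits against 30.2% of GC-matched windows (odds ratio 1.43, 95% confidence interval 1.14 to 1.77, exact p = 0.0013). This setting was chosen after the data had been seen, and random draws were made only for 100 bp. The planned comparison within 250 bp, against flanks, gave an odds ratio of 1.15 (exact p = 0.248). Within 100 bp and without the summits at small RNA genes, the odds ratio against GC-matched windows was 1.06 (exact p = 0.754).

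Among all 2080 words of 6 bases, 144 differed between IDR summits and GC-matched windows (Fisher's exact test with Benjamini-Hochberg adjustment), 105 of them more frequent at IDR summits. GTTCGA led (27.7% against 9.02%, odds ratio 3.86, adjusted exact p = 5.8e-20), followed by CGAACC (21.3% against 5.90%, adjusted p = 3.0e-18). Both occur in the B box, the internal promoter element of tRNA genes. Without the summits at small RNA genes 2 words passed, ATGCGC (11.6% against 4.06%, adjusted exact p = 0.0099) and CGCGCA (12.7% against 5.29%, adjusted p = 0.0276). In replicate 1 alone 35 words passed.

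The loci from which the transgene was built had no IDR region within 20 kb, and within 40 kb *fkh-3* had 1, of rank 122. *fkh-3* (X, 13421822 to 13423440) had 18 pooled regions within 20 kb, a number that 20.2% of 1000 random protein-coding genes reached, and the best of them ranked 894. *unc-119*, the rescue marker (III, 10902641 to 10908935), had 10, reached by 71.6%. *fkh-4*, the neighbour of *fkh-3*, had 19, reached by 15.9%. They included the IDR region of rank 122, which lay 19986 bp from *fkh-4*. That region was at a tRNA gene, with *set-8* as the nearest protein-coding start. *fkh-5* had 11, reached by 65.2%, with 5 in replicate 1 alone (95.4%) and 13 in replicate 2 alone (51.4%). In replicate 2 alone *fkh-3* had 23 regions, reached by 4.8%, and *fkh-4* 25, reached by 2.3%, and in replicate 1 alone *fkh-3* had 17, reached by 23.8%, and *fkh-4* 19, reached by 15%. Among the 5000 highest pooled regions *fkh-3* had 7, reached by 2.2%, and *fkh-4* 8, reached by 0.7%, a setting chosen after the data had been seen.

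The replicates shared a limited part of their highest regions. Of the top 441 regions of replicate 1, 185 (42%, exact 95% confidence interval 37.3 to 46.7%) had their summit in a top 441 region of replicate 2, against a mean of 0.79 and at most 4 after 100 circular shifts of replicate 2. Of the IDR regions, 253 (57.4%) were in the top 441 of replicate 1, 344 (78.0%) in that of replicate 2 and 188 (42.6%) in both. IDR regions at small RNA genes were in both top lists more often (58.2%) than other IDR regions (33.3%, odds ratio 2.78, p = 3.7e-07, Fisher's exact test). They also had higher signal, with 49.1% of the 220 highest IDR regions against 37.4% of all IDR regions, so gene type and signal are not separated here. This split was chosen after the data had been seen. On ce10, the other build deposited, the IDR list held 456 regions.

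**Figure D4:**
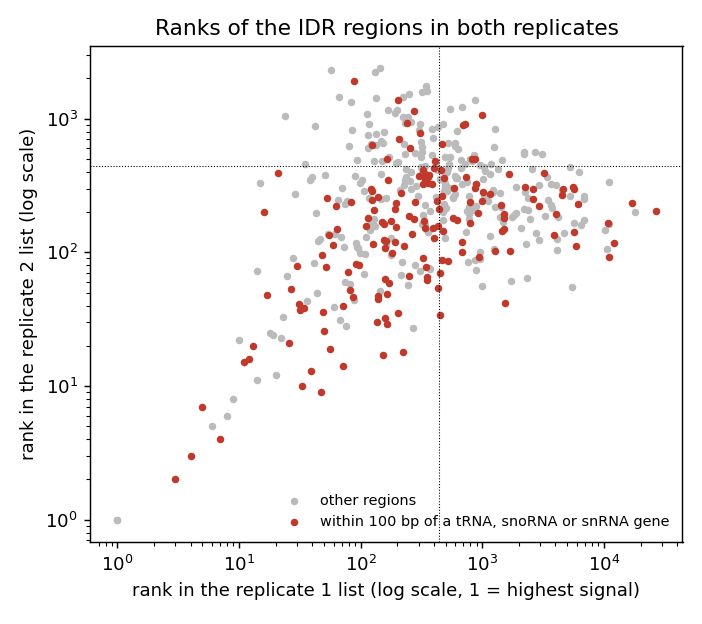
Rank of each of the 436 IDR regions found in both replicate lists (log axes, rank 1 is the highest signal), red for regions within 100 bp of a tRNA, snoRNA or snRNA gene and grey for others; dotted lines mark rank 441. Of all IDR regions, plotted or not, 58.2% of those at these genes and 33.3% of the others were within rank 441 in both replicates.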

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

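Settings without summits at small RNA genes, motif settings that change 2 choices together, the top 5000 regions at the transgene loci and all settings of the small RNA gene test were chosen after the data had been seen. No paired analysis was possible because there is 1 group. The annotation classes were not run on ce10, for which no annotation was used. The combined small RNA gene enrichment passed under every setting run, and for snRNA genes alone it was lost with a window of 0 bp (odds ratio 3.36). The cause of the changes below was not tested, except that the stricter list and the settings without small RNA summits test fewer regions.

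Replicate sharing moved to 53% for N = 100, 37.1% for N = 1000, 31.3% for N = 5000 and 36.7% with summits within 100 bp. The promoter odds ratio was 1.32 to 1.46 leaving out each replicate and 1.07 with the narrow window. Against random positions, odds ratios were 0.787 for coding exons, 0.645 for introns and 0.753 for intergenic sequence. Without small RNA summits they were 2.53 for 5'UTRs, 0.43 for introns, 1.36 for intergenic sequence and 0.545 for X. Against gene number X was at 1.55. The count of gene lists passing was 0 to 1 leaving out each replicate, and 1 with the stricter list, with both other windows, with all protein-coding genes as background and without small RNA summits.

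The forkhead motif odds ratio, 0.552 against flanks, turned above 1 in other settings. Against flanks it was 1.15 with 250 bp each side (exact p = 0.248) and 1.15 for GTAAACA (p = 0.711). Against GC-matched windows it was 1.33 (exact p = 0.0942), 1.51 for GTAAACA (p = 0.257) and 1.06 without small RNA summits (p = 0.754). Only the 1.43 for 250 bp against GC-matched windows had a p under 0.05 (exact p = 0.0013). Random draws also lay below their flanks (0.491 to 0.906), so the turn alone does not show enrichment. Words passing numbered 693 against flanks, 92 in the stricter list, 2 without small RNA summits and 35 to 128 leaving out each replicate. Regions near *fkh-3* numbered 17 to 23 leaving out each replicate, and 7 in the top 5000. Unknown read depth limits all of these.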

Other observations

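Tests of tRNA isotypes, of tRNA and snoRNA summits apart, of the strain, of copies of the *snpc-4* neighbourhood, of intron sequence and of settings without small RNA summits were chosen only after the results were seen, and so was the use of the planned tests of ribosomal protein genes and GC-matched windows to weigh explanations. Among 21 tRNA isotypes, tRNA-Ala genes had an IDR summit most often, at 16 of 34 (47.1%) against 17.1% of other tRNA genes (odds ratio 4.31, adjusted p = 0.0021, Fisher's exact test). It was the only isotype to pass. The share was 26.5% against 10.6% in the top 441 of replicate 1 (exact p = 0.0105) and 38.2% against 16.4% in those of replicate 2 (p = 0.0039), while in the whole pooled list it was 79.4% against 67.9% (p = 0.186). The 16 genes rest on 15 summits, and their sequences resemble each other, so they are not independent. On X 21.7% of tRNA genes had an IDR summit, against 16.1% on autosomes (exact p = 0.0769).

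Why IDR summits concentrate at small RNA genes may have technical explanations. Reads shared between similar gene copies are argued against for snoRNA genes, whose summit windows had a median of 0% of 36-base words recurring in the reference. They stay open for tRNA genes, with 25.9%, and for all 165 summits together, with 18.7%, both between the limits set for the test (10 and 50%). The upper limit could not decide for tRNA genes. The windows are much longer than a typical tRNA gene, so copies of the gene without its flanks could not bring the share to 50%. A share of 25.9% therefore does not mean that only part of the gene recurs. tRNA genes with and without an IDR summit had the same median, 28.9%. Recovery of highly transcribed genes whatever the tagged protein cannot be told apart from binding by FKH-3, because no untagged library was analysed here. The ribosomal protein list had an odds ratio of 5.36 (95% confidence interval 1.84 to 12.9) but did not pass (adjusted exact p = 0.0527). It passed under most other settings, among them replicate 2 alone (adjusted exact p = 0.0044), but not in replicate 1 alone (adjusted exact p = 0.115). The other lists had too few members with a summit to decide. A strain with another tagged protein under this label also stays open. Of random genes, 20.2% had as many pooled regions as *fkh-3*. Over 18 combinations of list and window this share ran from 2.2 to 61.3%, with 2 under 5%. For the neighbour *fkh-4*, whose windows overlap those of *fkh-3*, it ran from 0.7 to 61.3% over the same combinations. The windows are nested and the lists overlap, so neither the lowest nor the highest values decide whether another strain was used. No biological explanation was tested, since the design has 1 group.

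For the region inside *snpc-4*, extra copies of its whole neighbourhood are argued against as the only source of its signal. Such copies would raise signal over the neighbourhood, but the region spans 678 bp. Within 40 kb of the gene the IDR list held only the 2 summits of this region. Among the 5000 highest pooled regions 3 lay within 40 kb, against a median of 4 for random genes. These values were picked after the data had been seen. A smaller contribution of copies stays open. In the pooled list 42.9% of random genes had as many regions within 20 kb, and 19.2% in replicate 1 alone. The same measure found no clear excess at *fkh-3* (20.2%), where the labelled transgene would add copies. In replicate 2 alone and in the top 5000, where *fkh-3* was at 4.8% and 2.2%, *snpc-4* was at 36.8% and 35.4%, which goes against extra copies. But these are the only 2 of 18 combinations with *fkh-3* under 5%, so they do not decide it. The limit written for arguing against extra copies, more than 20%, was met, but it was set aside after the values were seen because of *fkh-3*. Reads shared with another copy in the reference are argued against, because 0% of the region's 36-base words recur. Spliced copies such as complementary DNA may still contribute: the region includes 117 bp of intron, but both summits are in exons. The cause stays open, and no biological explanation was tested.

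The forkhead motif below its flanks is a pattern that random regions of the pooled list show too (odds ratios 0.491 to 0.906 in 20 draws), so it says little about FKH-3. Base composition could account for it. Against GC-matched windows within 100 bp the odds ratio of 1.33 lay above the 20 random draws (0.637 to 1.19), but its interval included 1. The interval of the odds ratio of 1.43 within 250 bp (exact p = 0.0013), a setting chosen after the data had been seen, did not. But random draws were made only for 100 bp, and the planned comparison within 250 bp, against flanks, gave 1.15 (exact p = 0.248). The 250 bp setting was not run without the summits at small RNA genes. Dilution by summits at small RNA genes cannot be told apart from other causes here: without them the odds ratio against flanks was 0.527, inside the range of the random draws. Against GC-matched windows it was 1.06 (95% confidence interval 0.683 to 1.60) without them and 1.33 (0.947 to 1.85) with them. Dilution would move it up, but the intervals overlap. A limit set in advance for that test, an upper bound under 1, was met but was wrong, since random regions meet it as well. No biological explanation was tested.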
